A study of Mus musculus with 5 samples.

How the data were processed

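UMI counts per gene and barcode were taken from 2 tables deposited by the authors, 1 of the 4 healthy mouse kidney libraries (11395 barcodes, 19713 genes) and 1 of the UUO library (6147 barcodes, 21516 genes), with 18249 genes in both. Per the deposited readme, the values are raw UMI counts made by the authors with the zUMIs pipeline, and per the submitters' processing notes STAR 2.5.3a and genome build mm10 were used. Whether intronic reads were counted, the gene annotation, the barcode and gene filters and the clustering are not given in the sources used here. Per the labels' protocols, cells came from enzymatic digestion and were sorted on light scatter, and nuclei came from detergent lysis and homogenization. The values were whole numbers, and 0 columns of values belonged to no sample. Among the rarest genes of each healthy nucleus library the commonest number of barcodes was above 1, a pattern that a gene filter leaves, so a gene at 0 over such a library is called listed at 0 and has no fold.

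Cell classes were those of the authors' deposited annotation. Segment and state labels of the proximal tubule, intercalated subtypes and fibroblast clusters were summed to broad classes, and a macrophage label with a damaged character in the UUO annotation was read as macrophage. The UUO label DL and tAL was placed in the descending limb class and TAL in the ascending limb class, beside the healthy labels LH(DL) and LH(AL). No barcode was removed and no doublet caller was run. Barcodes with more than 3 times the median UMIs of their class, where doublets would fall, numbered 53 in Drop-seq, 171 in sNucDrop-seq, 186 in DroNc-seq, 43 in healthy 10x and 202 in UUO, and an alternative left them out. The Drop-seq barcodes had between 501 and 1998 genes.

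With 1 library per group there was no test. Counts were summed over the barcodes of a class and library and scaled to all UMIs of the sum, as CPM. Shares carry exact Clopper-Pearson 95% intervals and sums exact Poisson intervals, and the log2 ratio of 2 sums an exact interval conditional on their total. All of these cover counting error only. A gene was measured where both libraries listed it and the 2 sums held at least 20 counts. The counts behind an unlisted gene's floor were 3 in Drop-seq, sNucDrop-seq and UUO, 10 in DroNc-seq and 11 in healthy 10x.

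Before the data were examined, 31 gene lists, the rule for named genes, the comparisons and most alternatives were fixed. A list is described by its median log2 ratio, the members at least 2-fold higher or lower, the percentile of the median among 10000 random lists of the same size matched on mean CPM in 20 bins, and the range of the median over 2000 resamplings of its members. Those ranges describe the spread of members, which are not replicates. Lists with fewer than 3 measured members have no median. Named genes were the 6 highest and 6 lowest by the interval bound nearest to 0, leaving out mitochondrial, ribosomal protein and unnamed gene models, and per list up to 4 members with the largest mean CPM plus members at least 4-fold apart with at least 20 counts. Some genes that these rules name are not reported here. Genes that lead a class were chosen after their values were seen.

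For genes per barcode, UMIs were drawn without replacement to 500 per barcode, shallower barcodes were left out, and intervals came from 1000 resamplings of barcodes. Gene lengths and places came from a GENCODE annotation of mm10. Label profiles of the healthy and UUO annotations were compared over genes with a mean of at least 20 CPM after adding 10 CPM. In data simulated from the sums with 200 genes changed, the interval lay clear of 0 for 84.8% of 2-fold changes in the cells and sNucDrop-seq comparison (13168 genes), 80.9% in the UUO proximal tubule comparison (11582) and 92.9% in the UUO comparison over all nuclei (12976), and for 100%, 100% and 99.0% of 4-fold changes.

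Alternatives were TMM and median-of-ratios scaling, totals without mitochondrial and ribosomal protein genes, a mean of CPM over barcodes, barcode minimums of 500 and 1000 UMIs, barcodes without the high ones, count minimums of 1 and 100, thinning to 300 and 1000 UMIs, shares outside the proximal tubule, and the proximal tubule without its injured or dividing labels. Others were chosen after seeing the data: totals over genes listed in both libraries, totals without Malat1, label levels of lists without Spp1, shares without ascending limb barcodes that hold more red blood cell than ascending limb counts, listed zeros set at the floor, and sNucDrop-seq or DroNc-seq nuclei as the healthy reference. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM, were used.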

Results

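The data were UMI counts per gene for 17542 barcodes from mouse kidney, in 5 libraries with 1 library per group. From healthy kidney there was a Drop-seq library of whole cells (3531 barcodes) and 3 libraries of isolated nuclei, made by sNucDrop-seq (3011), DroNc-seq (2769) and the 10x Chromium droplet system (2084). A further 10x library of nuclei (6147) came from kidney 14 days after unilateral ureteral obstruction (UUO), a surgical injury that dilates the tubules and scars the kidney. The Drop-seq library held 6872118 UMIs, the sNucDrop-seq library 4630236, the DroNc-seq library 5864130, the healthy 10x library 2947137 and the UUO library 7411036. The median barcode held 1630 UMIs in Drop-seq, 1143 in sNucDrop-seq, 1598 in DroNc-seq, 1162.5 in healthy 10x and 1055 in UUO. Because each group had 1 library, no difference has a replicate check, and every interval covers counting error only. Levels are CPM, the count of a gene scaled to the total UMIs of the barcodes summed.

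Whole cells and nuclei were compared first for the cell types they captured. Drop-seq cells were mostly proximal tubule, the segment that reabsorbs most of the filtered solute. Its labels were on 85.6% of barcodes (exact 95% interval 84.4 to 86.7), against 60.5% (58.7 to 62.2) in sNucDrop-seq, 58.0% (56.1 to 59.8) in DroNc-seq and 33.8% (31.8 to 35.9) in 10x nuclei. Podocytes, the filtering cells of the glomerulus, made up 0.0566% of Drop-seq barcodes (2 cells, 0.00686 to 0.204). They were 1.83% (1.38 to 2.37), 2.82% (2.23 to 3.5) and 2.54% (1.91 to 3.31) of the sNucDrop-seq, DroNc-seq and 10x nuclei. Endothelial cells were 0.566% of Drop-seq barcodes (0.346 to 0.873) and 4.88%, 3.83% and 2.21% of the 3 nucleus libraries in the same order. Each segment downstream of the proximal tubule also had a lower share in Drop-seq than in each nucleus library, although for distal convoluted tubule and principal cells some of the intervals overlapped.

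The loop of Henle showed the widest span among those segments: its ascending limb was 3.63% of Drop-seq barcodes, 8.70% of sNucDrop-seq, 8.85% of DroNc-seq and 26.1% of 10x nuclei (24.2 to 28.0). Its descending limb was 0.453%, 1.89%, 3.32% and 5.71%. Distal convoluted tubule was 4.13%, 4.35%, 4.80% and 8.88% in the same order, and connecting tubule 2.75%, 5.35%, 4.23% and 6.67%. Principal cells were 1.05%, 2.39%, 1.81% and 5.57%, and acid- or base-secreting intercalated cells 1.02%, 3.82%, 5.16% and 7.63%. The S3 segment, the straight end of the proximal tubule, was 54.6% of Drop-seq barcodes, 29.4% of sNucDrop-seq, 10.6% of DroNc-seq and 12.1% of 10x nuclei. Macrophages were 0.566% of Drop-seq barcodes (0.346 to 0.873), 1.43% of sNucDrop-seq, 1.95% of DroNc-seq and 0.144% of 10x nuclei (0.0297 to 0.42). A label given as MC, whose meaning the labels do not spell out, was 0.198% of Drop-seq barcodes (0.0797 to 0.408), 4.88% of sNucDrop-seq, 5.27% of DroNc-seq and 0.768% of 10x nuclei. Some of the smallest classes were led by genes of other cell types. The 2 Drop-seq podocytes were led by proximal tubule genes such as Keg1 and Slc34a1, the 7 Drop-seq cells labelled MC by ribosomal and respiratory genes, and the 3 healthy 10x macrophages by Slc34a1, Ptprd and Slc12a3. The 128 Drop-seq ascending limb cells were led by Slc12a1 but had 4 haemoglobin genes among their 10 leading genes. Of their 1403 red blood cell counts, 1372 lay in 2 barcodes, and without these 2 the share was 3.57% (2.98 to 4.24), or 24.9% outside the proximal tubule. The 20 Drop-seq macrophages were led by the plasma cell genes Igkc, Igha and Jchain, followed by the macrophage genes Lyz2 and Cd74. Without the proximal tubule in the denominator, the podocyte share was 0.393% in Drop-seq against 4.62%, 6.70% and 3.84% in the nuclei. On that denominator the direction turned for some segments. Distal convoluted tubule was 28.7% in Drop-seq against 11.0%, 11.4% and 13.4%, and connecting tubule 19.1% against 13.5%, 10.1% and 10.1%. Ascending limb was 25.1% against 22.0%, 21.0% and 39.4%, and principal cells 7.27% against 6.05%, 4.30% and 8.41%, where the values higher in Drop-seq had overlapping intervals. Endothelium was 3.93% against 12.4%, 9.11% and 3.34%. With barcodes under 1000 UMIs left out, the proximal tubule share of the healthy 10x library was 39.5%.

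**Figure D1:**
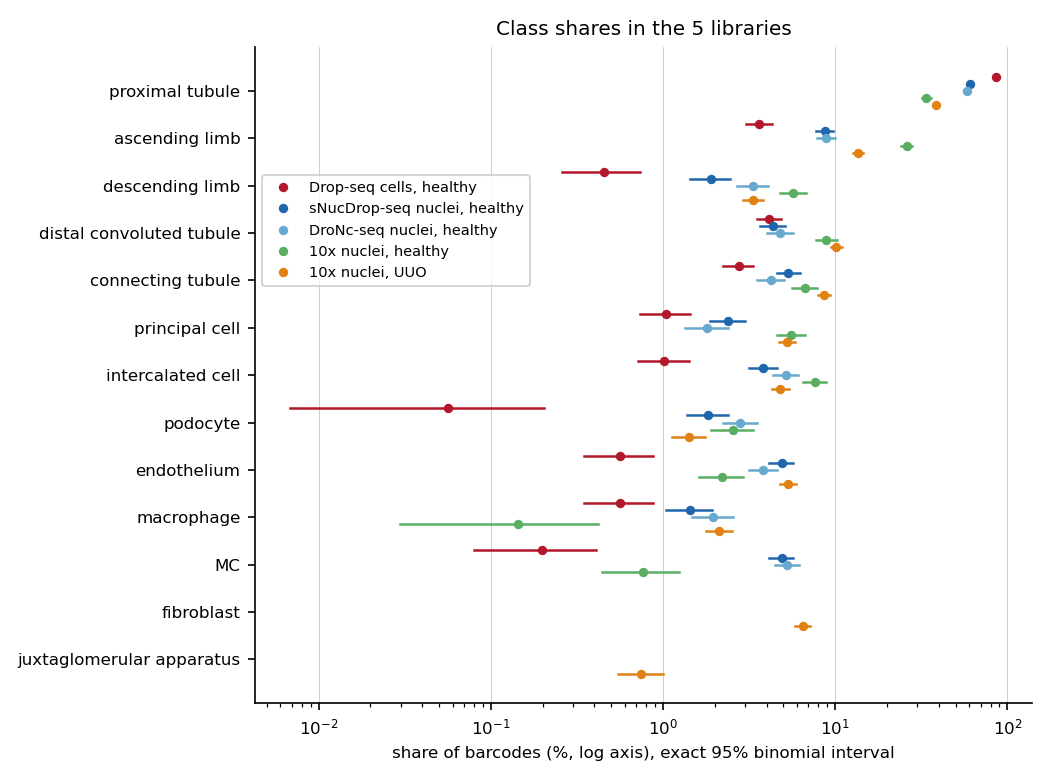
Share of barcodes in each cell class (percent, logarithmic axis) for the 5 libraries, with exact 95% binomial intervals. Podocytes were 0.0566% of Drop-seq cells and between 1.83% and 2.82% of the healthy nuclei, while proximal tubule was 85.6% of Drop-seq cells and between 33.8% and 60.5% of the healthy nuclei.

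Sensitivity was compared as the number of genes detected per barcode. The median barcode showed 812 genes in Drop-seq cells, 736 in sNucDrop-seq, 937 in DroNc-seq, 756.5 in healthy 10x and 715 in UUO nuclei. After each barcode was thinned to 500 UMIs, the medians were 320 genes (318 to 321) in Drop-seq, 375 (374 to 376) in sNucDrop-seq, 364 (363 to 365) in DroNc-seq, 371 (370 to 372) in healthy 10x and 381 (380 to 381) in UUO. Barcodes too shallow for this numbered 128 in healthy 10x and 801 in UUO and 0 in the other libraries. Transcripts of the mitochondrial genome took 24.3% of Drop-seq UMIs and at most 0.244% of the UMIs of any nucleus library. The nuclear-retained noncoding RNA Malat1 took 0.995% in Drop-seq, 10.8% in sNucDrop-seq, 15.3% in DroNc-seq and 8.36% in healthy 10x. When mitochondrial and ribosomal protein transcripts were left out before thinning, the order turned: Drop-seq gave 387 genes against 374, 363 and 370 in the healthy nuclei. That step took far more UMIs from Drop-seq than from nuclei and left Malat1 in, so the order depends on which abundant transcripts are removed.

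Within the proximal tubule, cells and nuclei were compared to ask how the transcripts of whole cells and nuclei differ, including genes that respond to tissue dissociation. Drop-seq cells held more immediate early and dissociation response transcripts, more chaperone, ribosomal protein and oxidative phosphorylation transcripts, and far more mitochondrial transcripts than sNucDrop-seq nuclei. Jun, a stress-responsive transcription factor, stood at 229 CPM in cells and 13.9 in nuclei (log2 ratio 4.04, 3.59 to 4.53). Nuclei held more of the nuclear noncoding RNAs, with Malat1 at 101860 CPM against 9610 and the paraspeckle RNA Neat1 at 1985 against 245, and more transcripts of podocyte, endothelial and matrix genes. The sums covered 3022 cells with 5895202 UMIs and 1821 nuclei with 2877594 UMIs, and 12838 genes were measured. Across genes, which are not independent replicates, the Spearman correlation of the 2 profiles was 0.65.

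The median gene had a log2 ratio of cells over sNucDrop-seq nuclei of -0.93, and 2 other scalings (TMM and median of ratios) raised every ratio by 1.08 and 1.07. Lists are therefore also given relative to that median. Of 17 immediate early and dissociation response genes measured, 8 were at least 2-fold higher in cells and 0 lower. Their median was 0.93 (1.87 relative to all genes, percentile 99.9 of 10000 random lists of like abundance). Beside Jun, Jund was at 99.7 against 16.3 CPM, Egr1 at 15.3 against 1.04 with 3 nuclear counts (log2 3.87, 2.28 to 6.18), and Klf4 at 13.6 against 2.09. Dusp1, a MAP kinase phosphatase, was at 61.2 against 48.3. The AP-1 genes Fos (39.5 CPM in cells) and Atf3 (6.11) were listed at 0 in the nuclei. No fold is given for them, because the table shows signs of a gene filter. Against DroNc-seq, 13 of 19 members were at least 2-fold higher in cells (median 1.49), and against 10x nuclei 6 of 12 (median 1.43), with 0 lower in either. Long genes were lower in cells. Over 5 groups of genes from shortest to longest, the median log2 ratio was 0.69, -0.48, -0.92, -1.43 and -1.99. The percentile of the immediate early list among lists matched on length was 42.6 against sNucDrop-seq nuclei, 81.6 against DroNc-seq nuclei and 23.4 against 10x nuclei. The values given below for the other lists in cells over nuclei, both higher and lower, are not matched on length. Gene length is therefore not separated from them.

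Among 12 chaperones measured, 7 were at least 2-fold higher in cells and 1 lower (median 1.22, 2.15 relative to all genes). The mitochondrial chaperonins Hspd1 (848 against 150 CPM) and Hspe1 (476 against 89.7) lay among the higher ones. The list median was 2.30 under either other scaling. All 8 mitochondrial transcripts measured were higher in cells (median 8.03), with mt-Cytb at 18651 against 45.2 CPM. Of 79 cytosolic ribosomal protein genes, 75 were at least 2-fold higher (median 2.13). Of 73 nuclear genes of oxidative phosphorylation, 67 were (median 2.69), among them Ndufa4 (1727 against 122 CPM). MHC class II and interferon response genes were higher in cells in 9 of 10 cases (median 2.08). B2m, the light chain of MHC class I, was at 300 against 32.3 CPM and H2-Ab1 at 48.9 against 4.52. Fatty acid oxidation genes divided. Of 20 measured, 8 were at least 2-fold higher and 3 lower (median 0.62, 1.56 relative to all genes). The medium-chain dehydrogenase Acadm was at 1158 against 245 CPM and the transcription factor Ppara at 92.8 against 938. The list median was -0.08 against 10x nuclei and positive there under the other scalings. The proximal tubule transporter and metabolism list had 7 members higher and 7 lower of 26, a median of -0.43 that became 0.65 under TMM and median of ratios. Kap, an androgen-responsive proximal tubule transcript, was at 33787 against 3538 CPM and the phosphate transporter Slc34a1 at 2386 against 4992. Outside the proximal tubule, Kap was at 26.9% of its level inside in Drop-seq and at 87.7% in sNucDrop-seq, and Slc34a1 at 26.8% and 39.7%.

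Of 9 podocyte genes measured in the proximal tubule sums, 0 were higher in cells and 8 were at least 2-fold lower (median -3.97, -3.04 relative to all genes, percentile 0). Of 10 endothelial genes 9 were lower (median -3.36). Magi2, a scaffold protein of the podocyte slit diaphragm, stood at 76.0 CPM in cells and 1531 in nuclei, Nphs1 (nephrin) at 11.0 and 26.1, and the endothelial receptor Flt1 at 3.22 and 56.6. Lists of extracellular matrix (6 of 8 lower, median -3.00) and of profibrotic growth factors (7 of 9 lower, median -2.43) were also lower in cells. Slc12a1, the salt transporter of the thick ascending limb, was at 51.1 CPM in the proximal tubule cells and 694 in the proximal tubule nuclei. As a measure of free RNA, the proximal tubule list outside that class was at 27.3% of its level inside it in Drop-seq, 45.9% in sNucDrop-seq, 33.9% in DroNc-seq and 11.1% in 10x nuclei. Lists of thick ascending limb (5 of 7 lower, median -1.57), distal convoluted tubule (-2.54), principal cell (-2.08), intercalated cell (-2.44) and mesangial genes (-2.29) were likewise lower in cells. Tubule injury (-1.28), connecting tubule (-0.44), chemokine (-0.82), S1 and S2 segment (-0.81) and S3 segment lists (-0.93) had medians close to that of all genes. Each of these except the injury list turned positive under the other scalings.

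The genes highest in cells over sNucDrop-seq nuclei by the bound of their interval nearest to 0 were Myo3a (12191 against 125 CPM), Trhde (2555 against 23.6), Racgap1 (580 against 3.82) and Fam213b (104 against 2.09). So were Dyrk3 (153 against 0.348; 1 nuclear count, log2 8.78, 6.30 to 14.09) and the haemoglobin gene Hbb-bs (88.0 against 0.695; 2 nuclear counts, log2 6.98, 5.12 to 10.03). The lowest included Slc8a1 (7.97 against 872 CPM), Trim30a (6.28 against 702) and genes with at most 3 counts in cells. Those included Anln (0.509 against 153 CPM; 3 counts in cells, log2 -8.23, -10.51 to -6.67), Gata4 (0.509 against 109; 3 counts, log2 -7.74, -10.03 to -6.18) and Tshz3 (0.170 against 53.9; 1 count, log2 -8.31, -13.62 to -5.81). Anln and Racgap1 are known for roles in cell division. Of 13 cell cycle genes measured 1 was at least 2-fold higher in cells and 9 lower (median -1.75). Values of single genes at these extremes are uncertain, because the authors' assignment of intronic, overlapping or antisense reads is not given in the sources used here.

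**Figure D2:**
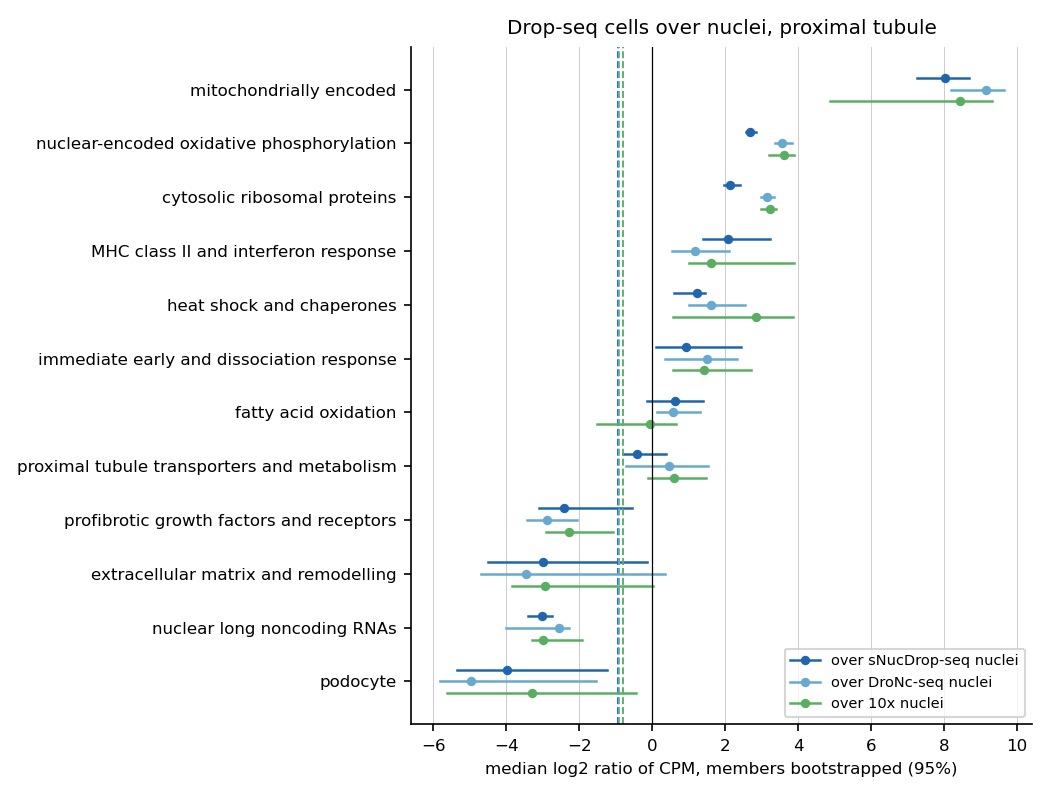
Median log2 ratio of CPM per gene list for proximal tubule Drop-seq cells over nuclei of each of 3 platforms, with 95% ranges from resampling list members; dashed lines mark the median of all genes. Against sNucDrop-seq nuclei, immediate early (0.93), heat shock (1.22), ribosomal (2.13) and oxidative phosphorylation lists (2.69) lay above 0 and podocyte genes below (-3.97), whereas the sign of the proximal tubule list there (-0.43) and of the fatty acid oxidation list against 10x nuclei (-0.08) flips under TMM and median of ratios.

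The 3 nucleus platforms were compared in healthy proximal tubule to see how far nuclei of different methods differ. DroNc-seq and sNucDrop-seq were the closest pair, with a Spearman correlation across genes of 0.93, against 0.79 for 10x with sNucDrop-seq and 0.82 for 10x with DroNc-seq. S3 segment genes were lower in both other platforms than in sNucDrop-seq (median -4.37 in DroNc-seq, 5 of 6 lower; -3.03 in 10x, 4 of 5 lower). The proximal tubule class differed in make-up, with S3 labels on 884 of 1821 nuclei in sNucDrop-seq, 294 of 1605 in DroNc-seq and 253 of 705 in 10x. Within S3 labels alone, the list proximal tubule S3 segment summed to 5086 CPM in sNucDrop-seq, 775 in DroNc-seq and 1077 in 10x. Slc7a13, a cystine carrier of that segment, was at 730 CPM in sNucDrop-seq, 3.93 in DroNc-seq and listed at 0 in 10x. The steroid hydroxylase Cyp7b1 was at 448, 13.6 and 29.5 CPM. Kap was at 3538 CPM in sNucDrop-seq, 461 in DroNc-seq and 328 in 10x. Outside the proximal tubule it was at 87.7%, 61.2% and 64.0% of these levels, so much of them may be free RNA. Ribosomal protein genes (median -1.04 in DroNc-seq and -1.07 in 10x) and chaperones (-0.79 and -1.86) were lower than in sNucDrop-seq. Slc34a1 was at 4992 CPM in sNucDrop-seq, 3905 in DroNc-seq and 8639 in 10x. The endocytic receptor Lrp2 was at 1210 CPM in sNucDrop-seq and 3233 in 10x. These libraries also differed in sex-linked transcripts. Xist, made from the inactive X chromosome, was at 1309 CPM over DroNc-seq and 1321 over healthy 10x nuclei and had 0 counts in Drop-seq and sNucDrop-seq. In turn 4 Y-linked genes summed to 145 CPM in Drop-seq, 446 in sNucDrop-seq, 8.70 in DroNc-seq and 3.73 in healthy 10x. Platform and this difference go together in the design.

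UUO was then compared with healthy 10x nuclei, first for cell types. Without a depth minimum, nuclei labelled macrophage or endothelium made up more of the UUO library. The label MC, which the UUO annotation lacks, was on 0.768% of healthy 10x nuclei. Fibroblast labels, which the healthy annotation lacks, were on 6.47% of nuclei (5.87 to 7.12), with 330 nuclei of Fib.1 and 68 of Fib.2. The list fibroblast and pericyte summed to 1622 CPM in Fib.1 and 146 (84.9 to 233) in Fib.2, near the 138 of UUO endothelium, so Fib.2 is a fibroblast class by its label only. Without barcodes above 3 class medians of UMIs, where doublets would fall, Fib.2 was 43 nuclei (0.723%) and Fib.1 295 (4.96%). A macrophage label was on 2.11% (1.77 to 2.51) against 0.144% (0.0297 to 0.42) in healthy 10x. Endothelial nuclei were 5.30% (4.76 to 5.89) against 2.21% (1.62 to 2.93), and podocytes 1.42% (1.14 to 1.74) against 2.54% (1.91 to 3.31). Ascending limb was 13.5% (12.7 to 14.4) against 26.1%, descending limb 3.33% against 5.71%, intercalated cells 4.80% against 7.63%, and connecting tubule 8.61% against 6.67%. The UUO ascending limb class was the label TAL alone, and its descending limb class the label DL and tAL, read as descending and thin ascending limb. The healthy labels LH(AL) and LH(DL) do not say where thin ascending limb was placed, so the limb shares may not compare like with like. Distal convoluted tubule was 10.2% against 8.88%, principal cells 5.24% against 5.57%, and the juxtaglomerular apparatus, a label of the UUO annotation alone, 0.748%. Proximal tubule labels covered 38.3% of UUO nuclei (37.0 to 39.5) against 33.8%, including nuclei labelled dedifferentiated (1.90%) and proliferating (1.32%) that the healthy annotation does not use. The classes differed in depth, with median UMIs of 326.5 in UUO macrophages, 514.5 in Fib.1 and 1412 in UUO proximal tubule. With nuclei under 1000 UMIs left out the UUO shares were 57.9% proximal tubule and 3.79% fibroblast, made up of Fib.1 at 2.11% and Fib.2 at 1.69%. Endothelium was then 2.29% (1.81 to 2.85) against 1.2% (0.675 to 1.98), and at a minimum of 500 UMIs 3.27% (2.81 to 3.79) against 2.15% (1.55 to 2.89), with overlapping intervals at both. Macrophages were then 0.241% (0.104 to 0.474) against 0.161% (0.0194 to 0.579) in healthy 10x, and at a minimum of 500 UMIs 0.337% (0.200 to 0.532) against 0.153% (0.0316 to 0.448), so a higher share in UUO was not detected there. The 3 healthy 10x nuclei with this label were led by Slc34a1, Ptprd and Slc12a3, so the healthy share may not count macrophages. At 1000 UMIs the direction turned for 3 classes. Distal convoluted tubule was 5.45% (4.70 to 6.27) against 10.1% (8.49 to 11.9), connecting tubule 7.10% against 7.87% with overlapping intervals, and principal cells 6.29% against 2.97%.

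In proximal tubule nuclei, UUO was compared with healthy kidney for genes of transport and metabolism and for genes of tubule injury. Of 24 transporter and metabolism genes measured, 20 were at least 2-fold lower in UUO and 1 was higher. The median was 9.77-fold lower (log2 -3.29, -3.19 relative to all genes, percentile 0 of 10000 random lists). Slc34a1 stood at 226 CPM in UUO and 8639 in healthy nuclei (log2 -5.26, -5.36 to -5.16), and Miox, which starts inositol breakdown, at 4.13 and 1053. Tubule injury genes were higher in UUO in 15 of 18 cases, and their median was 12.6-fold higher (log2 3.65, percentile 100). The secreted phosphoprotein Spp1 was at 2697 CPM against 90.9 (log2 4.89, 4.62 to 5.18) and Havcr1, which encodes the injury marker KIM-1, at 255 against 19.4 (log2 3.72, 3.13 to 4.39). Free RNA was not removed from these sums. In UUO podocytes and endothelium Spp1 was at 2862 and 3977 CPM, above proximal tubule, and Havcr1 at 81.5 and 63.0, below it. The sums covered 2352 UUO nuclei with 3635279 UMIs and 705 healthy nuclei with 1187607 UMIs, and 11395 genes were measured. The median gene had a log2 ratio of -0.10, which TMM raised by 0.17 and median of ratios by 0.19.

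Also lower in UUO proximal tubule were the citrate and dicarboxylate carrier Slc13a3 (5.78 against 641 CPM), and the endocytic receptors Lrp2 (406 against 3233) and Cubn (76.8 against 880). So were the gluconeogenic enzymes Pck1 (9.08 against 579) and Fbp1 (7.43 against 356) and the organic anion transporter Slc22a6 (0.275 against 78.3; 1 count in UUO, log2 -8.15, -13.47 to -5.64). The sulfate transporter Slc13a1 (1035 against 701 CPM) and the bicarbonate transporter Slc4a4 (1374 against 1062) were higher, though slightly lower against sNucDrop-seq nuclei (log2 -0.18 and -0.06). The 1 member at least 2-fold higher was Acsm3 (log2 1.05 with 3 healthy counts, -0.72 to 3.45), and against sNucDrop-seq nuclei it was at -5.38. Fatty acid oxidation genes were at least 2-fold lower in 13 of 18 cases and higher in 0 (median -1.34). Ppara was at 60.5 against 555 CPM, Acadm at 17.3 against 163 and the omega-hydroxylase Cyp4a14 at 0 counts against 248 CPM. Nuclear oxidative phosphorylation genes were lower in 19 of 71 and higher in 0 (median -0.67). The class differed in make-up, with S3 labels on 473 of 2352 UUO nuclei and 253 of 705 healthy 10x nuclei. S1 and S2 segment genes had a median of -2.67, with 4 of 6 lower. The S3 list had 2 members higher and 2 lower of 5. Its median of -0.37 became 0.34 when members listed at 0 were set at the smallest level the library could list, and -3.71 against sNucDrop-seq nuclei. Against sNucDrop-seq nuclei, which carry Y-linked transcripts as the UUO nuclei do, the transporter list median was -5.38 and the injury median 4.52. Of the 24 transporter genes, 19 were at least 2-fold lower against both references.

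Among the genes higher in UUO proximal tubule, Il34, a macrophage growth factor, was at 2519 CPM against 87.6, Dcdc2a at 1350 against 69.1, clusterin (Clu) at 331 against 20.2 and Anxa2 at 242 against 10.1. The adhesion molecule Vcam1 (743 CPM in UUO), Lcn2, a siderophore-binding protein of injured tubule (133), Cd44 (127), the transcription factor Sox9 (32.2) and the neutrophil chemokine Cxcl1 (122) were listed at 0 in the healthy library. In UUO podocytes and endothelium, Clu was at 489 and 764 CPM and Lcn2 at 234 and 339, above proximal tubule. Il34 (652 and 532) and Vcam1 (153 and 228) were below it there. Of 8 chemokine, cytokine and complement genes measured, 7 were at least 2-fold higher and 0 lower (median 2.83). Of 13 profibrotic growth factors and receptors, 7 were higher and 0 lower (median 1.08), among them Pdgfd (1431 against 64.0 CPM), Pdgfb (64.9 against 10.1) and Tgfb2 (39.9 against 3.37). MHC class II and interferon response genes were higher in 4 of 6 (median 1.97), with H2-K1 at 224 against 10.1. The NF-kappaB subunits Relb (140 against 5.89 CPM) and Nfkb1 (265 against 61.5) were also higher. Immediate early genes were higher in 8 of 13 and lower in 1 (median 1.90, or 0.65 with listed zeros at the smallest listed level and 0.98 against sNucDrop-seq nuclei). Myc was at 53.9 against 4.21 CPM, Klf6 at 134 against 13.5 and Gadd45g at 28.9 against 119. Extracellular matrix genes were higher in 4 of 14 and lower in 1 (median 0.69), the lower one being Timp3, an inhibitor of matrix proteases (53.1 against 240 CPM). Cell cycle genes were higher in 5 of 11 (median 0.86), and ribosomal protein genes in 41 of 76 (median 1.04, but 0.07 against sNucDrop-seq nuclei). Chaperones had a median of -0.34, and -1.86 against sNucDrop-seq nuclei. Against DroNc-seq nuclei the chemokine median was 1.52 and the MHC and interferon median 0.98.

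By the bound nearest to 0, the genes highest in UUO proximal tubule were the potassium channel and channel-associated genes Kcnip4 (3557 against 37.1 CPM) and Kcnh8 (517 against 4.21), the sorting receptor Sorcs1 (985 against 13.5), the Y-linked Uty (384 against 5.05), Dock10 (928 against 17.7) and Spp1. The lowest were Miox and genes with at most 2 counts in UUO. Those were Xist (0.275 against 1580 CPM; 1 count, log2 -12.49, -17.79 to -10.01), the retinol dehydrogenase family member Rdh16f2 (0.550 against 600; 2 counts, log2 -10.09, -13.14 to -8.23) and the glycosyltransferase Ugt3a1 (0.275 against 228; 1 count, log2 -9.70, -15.01 to -7.21). Also among them were the organic anion transporter family members Slc22a19 (0.550 against 294; 2 counts, log2 -9.06, -12.11 to -7.20) and Slc22a29 (0 counts against 126 CPM). Rdh16f2, Slc22a19 and Slc22a29 have close paralogs, so reads shared between copies make their values uncertain. The 2 libraries thus differed in sex-linked transcripts, which the design does not separate from obstruction. Markers of other tubule segments in these sums were lower in UUO as well, with thick ascending limb genes in 6 of 6 (median -4.68), connecting tubule genes in 4 of 5 (-4.61) and principal cell genes in 6 of 6 (-2.28).

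**Figure D3:**
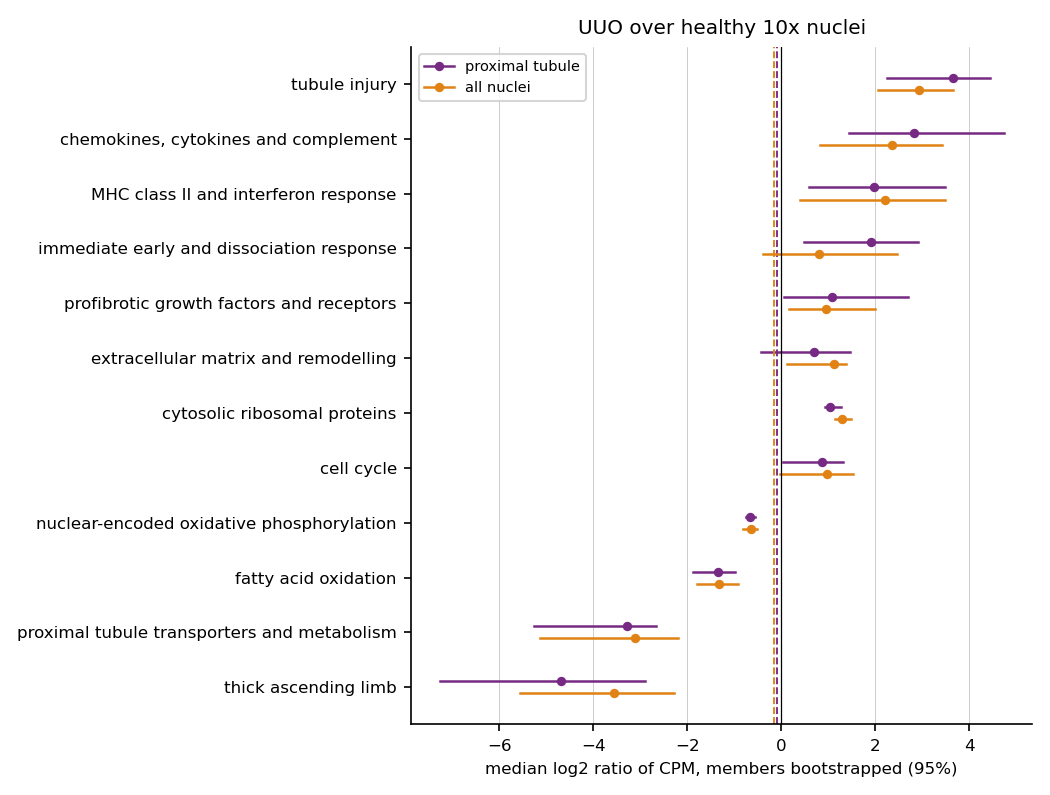
Median log2 ratio of CPM per gene list for UUO over healthy 10x nuclei, in proximal tubule nuclei and over all nuclei, with 95% ranges from resampling list members; dashed lines mark the median of all genes. Injury genes lay at 3.65 and 2.94 and proximal tubule genes at -3.29 and -3.12 in the proximal tubule and over all nuclei.

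Over all nuclei, the UUO library differed from the healthy 10x library in the same lists, with matrix genes further apart. Of 15 extracellular matrix genes measured, 8 were at least 2-fold higher and 1 lower (median 1.12). Fibronectin (Fn1) was at 31.0 against 3.39 CPM, Col1a2 at 22.0 against 4.41 and Bgn at 20.4 against 4.41. Col3a1 (36.3 CPM) and Col1a1 (16.9) were listed at 0 in healthy nuclei. The lower one was Timp3 (39.7 against 151 CPM). Injury genes were higher in 15 of 18 (median 2.94), with Lcn2 at 204 CPM and listed at 0 in healthy nuclei, and Clu at 526 against 27.8. The genes highest by the bound nearest to 0 were Uty (403 against 3.73 CPM), Kcnip4 (1905 against 30.2), Sorcs1 (535 against 11.5), Kcnh8 (286 against 7.46), Spp1 (3210 against 139) and the calcium-binding protein S100a6 (170 against 5.09). The lowest were Miox (2.43 against 497 CPM), the distal growth factor Egf (15.1 against 1845) and genes with at most 3 counts. Those were Xist (0.405 against 1321; 3 counts, log2 -11.67, -13.95 to -10.12), Rdh16f2 (0.270 against 274; 2 counts, log2 -9.99, -13.04 to -8.13), Ugt3a1 (0.135 against 107; 1 count, log2 -9.62, -14.93 to -7.14) and Slc22a19 (0.270 against 131; 2 counts, log2 -8.92, -11.97 to -7.06). Proximal tubule genes were lower in 19 of 24 (median -3.12), thick ascending limb genes in 7 of 7 (median -3.55) and intercalated cell genes in 7 of 9 (median -2.10). Fatty acid oxidation genes were lower in 13 of 18 (median -1.33), and ribosomal protein genes were higher in 61 of 77 (median 1.29). Ribosomal protein genes took 0.272% of UMIs in healthy 10x, 0.253% in DroNc-seq, 0.498% in sNucDrop-seq and 0.675% in UUO nuclei, so that difference depends on the healthy reference. Here 12831 genes were measured, and their median log2 ratio of -0.16 moved by 0.17 with TMM and by 0.19 with median of ratios.

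Distal segments were then compared class by class. Within ascending limb nuclei all 7 of its own marker genes measured were at least 2-fold lower in UUO (median -3.01). Slc12a1 was at 1276 CPM against 15400, uromodulin (Umod) at 82.2 against 663 and Egf at 40.5 against 5193. Distal convoluted tubule markers were lower in 4 of 4 (median -3.58), among them the thiazide-sensitive transporter Slc12a3 (1026 against 13544 CPM). Connecting tubule markers were lower in 4 of 5 (median -5.31). Slc8a1 was at 956 against 37888 CPM and Calb1 at 15.2 against 1926, with the calcium channel Trpv5 higher at 396 against 156. In principal cells the water channel Aqp2 was at 49.7 against 4084 CPM and 6 of 7 markers were lower (median -4.40). In intercalated cells 4 of 7 were lower (median -2.52), with the bicarbonate exchanger Slc26a4 at 346 against 3084. These class names were not shown to hold the same cells in both tables. In UUO the connecting tubule label was led by Mgat4c, Phactr1 and Trpv5 and also by Kcnh5, and Mgat4c and Kcnh5 were among the leading genes of healthy 10x principal cells. The UUO principal cell label was led by Tbx3os1, Aldh1a3 and Gpc5, with none of the principal cell list among its leading 10 genes. Healthy 10x principal cells correlated best with the UUO connecting tubule label (r 0.486 over 7132 genes), then with principal cells (0.437). The marker lists of podocytes and endothelium differed less, although over all genes measured these 2 classes had the lowest Spearman correlations of UUO with healthy nuclei (0.44 and 0.48). These 2 classes also had the fewest measured genes (2147 and 3418) and the smallest healthy sums (112059 and 54128 UMIs). Counting error alone lowers a correlation in small sums, so these values do not rank the classes by change. Podocyte markers had 1 member higher and 0 lower of 10 (median 0.32), with Magi2 at 48095 CPM against 31091. Endothelial markers had 2 higher and 1 lower of 9 (median 0.16, or -0.07 as a mean over nuclei), with Cdh5 at 283 against 37.0 and Pecam1 at 1051 against 259. The healthy Cdh5 level is 2 counts, so its fold is uncertain. The median of the injury list lay above 0 in every class compared, from 2.29 in endothelium and 2.61 in podocytes to 3.41 in intercalated cells and 4.09 in distal convoluted tubule. Free RNA was not removed: in UUO Spp1 was at 3977 CPM in endothelium and 2862 in podocytes, and Clu at 764 and 489. TMM moved the all-gene median by 0.32 in endothelium, 0.25 in principal cells and 0.15 in the descending limb, and median of ratios by -0.19 in podocytes.

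Within the UUO library, the 17 labels were compared to see which nuclei carried injury, cytokine, matrix and dividing-cell transcripts. The labels are the authors' annotation of these same nuclei, so the levels describe the labels and are no independent evidence for their names. The leading genes included Top2a in proliferating nuclei, Ccl2, Cd44 and Vcam1 in dedifferentiated nuclei and Ren1 in the juxtaglomerular apparatus. Nuclei labelled dedifferentiated proximal tubule were high in chemokines, cytokines and complement and in Vcam1 (1825 CPM, against 76.7 in principal cells). Spp1, which is in the chemokine list and in the injury list, weighed on these sums. With it, chemokines, cytokines and complement summed to 7659 CPM in dedifferentiated nuclei, 7734 in macrophages and 2866 in principal cells, of which Spp1 made 2416, 6254 and 2219. Without it they were at 5243 (4926 to 5575), 1480 (1194 to 1813) and 648, and next to dedifferentiated nuclei came PT(S2) at 3344. The dedifferentiated nuclei held Ccl2 at 802, Cd44 at 380 and Il34 at 3059 CPM. Their tubule injury genes summed to 11067 CPM (10605 to 11545), below Fib.2 at 12741 (12101 to 13405) and close to macrophages at 10916 and PT(S3) at 10306, with PT(S2) at 9855 and PT(S1) at 8084. Without Spp1 they were at 8651, Fib.2 at 9314, PT(S3) at 7706, PT(S2) at 7063, PT(S1) at 5263 and macrophages at 4663. Nuclei labelled proliferating proximal tubule held cell cycle genes at 2197 CPM (2004 to 2404), above macrophages at 732 and Fib.1 at 488, and had Top2a at 545 and Havcr1 at 582 CPM. Genes of extracellular matrix and remodelling were highest in Fib.1 at 3209 CPM (3002 to 3426), followed by Fib.2 at 2151, endothelium at 1591 and the juxtaglomerular apparatus at 1320, where renin (Ren1) was at 1639 CPM. The list of proximal tubule transporters and metabolism was at 8755 CPM in PT(S1), 3795 in PT(S2), 3740 in PT(S3), 3100 in dedifferentiated and 1800 in proliferating nuclei. Free RNA was not removed from these sums, and Spp1 was between 2170 and 6254 CPM in every label.

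**Figure D4:**
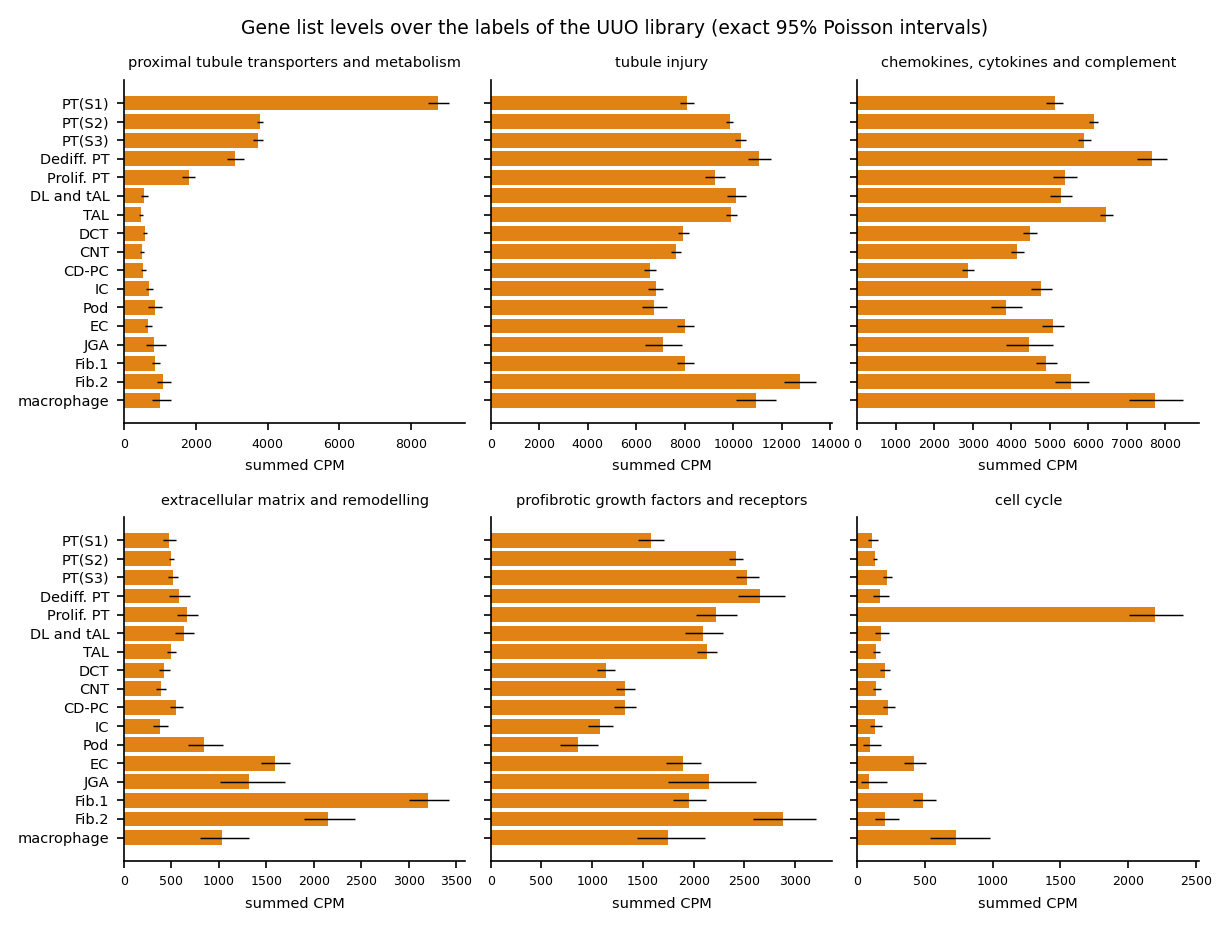
Summed CPM of 6 gene lists over the 17 labels of the UUO library, with exact 95% Poisson intervals; every horizontal axis starts at 0. Cell cycle genes peaked in proliferating proximal tubule (2197 CPM), extracellular matrix and remodelling genes in Fib.1 (3209 CPM), while chemokines, cytokines and complement reached 7734 CPM in macrophages, of which Spp1 made 6254, and 7659 CPM in dedifferentiated proximal tubule, of which Spp1 made 2416. The labels are the authors' annotation of these same nuclei, so the peaks are no independent evidence for the label names.

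In genome build mm10, some of the genes named above lie as follows: Slc34a1 on chromosome 13 at 55398187 to 55415592, Spp1 on 5 at 104435118 to 104441050, Havcr1 on 11 at 46735080 to 46779578 and Vcam1 on 3 at 116109949 to 116129688. Jun lies on 4 at 95049034 to 95052222, Xist on X at 103460366 to 103483254 and Uty on Y at 1096861 to 1245759. Nphs1 lies on 7 at 30458315 to 30487223, Malat1 on 19 at 5795690 to 5802672 and Il34 on 8 at 110741829 to 110805924. Slc12a1 lies on 2 at 125152505 to 125230002, Miox on 15 at 89334398 to 89337015 and Kcnip4 on 5 at 48389502 to 49524907.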

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

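These 7 genes of the fixed lists are listed only in the UUO table and so enter no comparison with a healthy library. They do count in the list levels over the UUO labels. Each is given because its level over the UUO library lies above the 0.405 CPM that 3 counts make there. No test in this part was chosen after its result was seen. The chemokine genes Ccl2 and Ccl7 were at 36.3 and 3.24 CPM. The protease inhibitor Timp1 was at 7.96 CPM. The cytokine gene Tnf was at 2.43 CPM. The mitotic cyclin Ccnb1 was at 1.08 CPM. The matrix proteoglycan gene Lum was at 0.540 CPM. Nkg7, a gene of cytotoxic lymphocytes, was also at 0.540 CPM, a level of 4 counts.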

How the results depend on the processing

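The sensitivity to processing was computed for 3984 values: 3539 stayed within their interval, 431 moved outside it and 14 reversed an order whose intervals had lain apart. In all, 146 medians, ratios or percents changed side. Among the 235 values that answer a comparison, 199 stayed, 34 moved and 2 reversed. Alternatives with sNucDrop-seq or DroNc-seq as reference, totals over shared genes, totals without Malat1, lists without Spp1, shares without 2 red blood cell barcodes, ratios of shares, and listed zeros at the floor were chosen after seeing the data. Over list medians, TMM moved 51 and kept 286, median of ratios 49 and 288, totals without mitochondrial and ribosomal genes 11 and 326, a mean over barcodes 13 and 324, a count minimum of 1 moved 8 and of 100 moved 4, leaving out high barcodes 5, totals without Malat1 moved 5 of 80, and sNucDrop-seq as reference 7 of 24. Leaving out injured or dividing labels moved 0. Cells against nuclei have no such labels to leave out. A minimum of 500 UMIs moved 1 list median and kept 331. It removed no barcode from Drop-seq, sNucDrop-seq or DroNc-seq, whose lowest barcodes held 678, 523 and 696 UMIs. Values from these libraries alone could not change under it, yet they count among those that stayed.

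Outside the proximal tubule, podocyte shares were 0.393% in Drop-seq, 4.62% in sNucDrop-seq, 6.70% in DroNc-seq and 3.84% in 10x nuclei, and UUO fibroblasts 10.5% and macrophages 3.43%, from the smaller denominator. That denominator reversed log2 ratios of shares, Drop-seq over sNucDrop-seq, to 0.19 for ascending limb, 0.49 for connecting tubule, 0.12 for macrophages and 0.26 for principal cells. Over DroNc-seq it gave 0.26 for ascending limb and 0.92 for connecting tubule, and over healthy 10x 0.25 for MC, 0.92 for connecting tubule, 1.10 for distal convoluted tubule and 0.24 for endothelium. At 1000 UMIs connecting tubule in UUO over healthy 10x reversed to -0.15. With a minimum of 500 UMIs the UUO shares were 43.4% proximal tubule, 4.53% fibroblast and 0.337% macrophage. With 1000 UMIs they were 57.9%, 3.79% and 0.241%, and healthy 10x proximal tubule was 39.5%. Without high barcodes UUO fibroblasts were 5.69%, with Fib.2 at 0.723%. Drop-seq genes per barcode, as a percent of sNucDrop-seq (85.3 at 500 UMIs), were 82.6 at 1000 UMIs and reversed to 103 without mitochondrial and ribosomal genes (107 of DroNc-seq). As a percent of healthy 10x (86.3) they were 86.9 at 300 UMIs, 84.4 at 1000 and reversed to 105 without those genes, and UUO over healthy 10x (103) was 102 at 300.

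In cells over sNucDrop-seq nuclei, TMM, median of ratios and totals without mitochondrial and ribosomal genes gave 2.30, 2.30 and 1.65 for heat shock, 3.21, 3.21 and 2.56 for ribosomal proteins and 3.76, 3.76 and 3.11 for oxidative phosphorylation, which was 2.49 as a mean over barcodes and 2.54 without Malat1 in the totals. The first 3 of these change every ratio by one factor. Against sNucDrop-seq nuclei the UUO transporter list was -5.38 and the injury list 4.52. Without Spp1 the injury list in dedifferentiated nuclei was 8651 CPM. As a mean over nuclei, Fib.1 matrix genes were 3474 CPM, cell cycle genes in proliferating proximal tubule 1855 CPM, and the endothelial list in endothelium -0.07. Lists left with fewer than 3 members gave no value. Where no denominator is named, the cause was not tested. No paired analysis was possible because each group has 1 library. Barcode number limits the rare classes: 2 Drop-seq podocytes (median 1782.5 UMIs, library 1630) and 3 healthy 10x macrophages (1135, library 1162.5).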

Other observations

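Chosen after the results were seen were the tests of gene length, of cell mix against all barcodes, of Malat1 in the totals, of the upper limit on genes, of free RNA, of the MC and Fib.1 labels, of sex as the whole cause and the comparison of UUO with sNucDrop-seq nuclei. Injury transcripts were higher in UUO outside the proximal tubule too. The median log2 ratio of the injury list was 3.30 in ascending limb, 3.02 in connecting tubule, 2.91 in principal cells and 2.65 in the descending limb, and ribosomal protein genes had medians from 1.09 in endothelium to 1.78 in distal convoluted tubule. The ribosomal values rest on healthy 10x as the reference, and in the proximal tubule the median of 1.04 was 0.07 against sNucDrop-seq and 1.11 against DroNc-seq nuclei. Oxidative phosphorylation genes had medians from -0.46 in intercalated cells to -0.76 in ascending limb, and fatty acid oxidation genes from -0.51 in endothelium to -1.66 in podocytes. Free RNA was not removed, and in UUO Spp1 was at 3977 CPM in endothelium, 2862 in podocytes and 6254 in macrophages, and Clu at 764 in endothelium and 489 in podocytes. Over all UUO nuclei the lymphocyte list had a median of 0.87 against healthy 10x nuclei and the cell cycle list 0.97.

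The UUO fibroblast labels differed from each other. Fib.1 was led by Csmd1, Lama2 and the collagen receptor Ddr2 and held the fibroblast and pericyte list at 1622 CPM, whereas Fib.2 was led by the matrix protein gene Tnc and by Wnt16 and also held the tubule genes Cdh6 at 3067 CPM and Dcdc2a at 2219 CPM. UUO macrophages were led by Ctss, Itgam and Mrc1 and held the macrophage list at 1273 CPM.

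Immediate early and dissociation response genes were higher in proximal tubule Drop-seq cells than in nuclei of all 3 platforms. Scaling by a few abundant transcripts is argued against, since the median against sNucDrop-seq nuclei was 2.01 under TMM, which can move it either way, and 0.79 without Malat1 in the totals (leaving out mitochondrial genes can only raise it). Cell mix stays open: the median of 0.93 within the class lay between the bounds of 0.5 and 1, and although class medians (0.93, 1.49 and 1.43 for sNucDrop-seq, DroNc-seq and 10x) were no lower than over all barcodes (0.70, 1.13 and 1.27), a class median less 0.5 times the median over all barcodes was as low as 0.59, with a range of -0.13 to 1.35 that includes 0. Gene length may account for the shift, because these genes are short and the percentile of their median among length-matched lists was at most 81.6 over the 3 platforms. A response of the tissue to dissociation remains untested, as no library separates it from the cell and nucleus difference.

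Podocytes were 0.0566% of Drop-seq cells and 1.83% to 2.82% of nuclei. Podocyte transcripts over all barcodes were also lower in Drop-seq, with list medians of -5.13 or below against each nucleus library. The median gene was itself at -1.03, -1.07 and -1.03 there against sNucDrop-seq, DroNc-seq and 10x nuclei. The podocyte list was also far lower in cells within proximal tubule barcodes, as given above. A cell and nucleus difference is therefore not separated from missing podocytes, and labels alone stay open. Among Drop-seq cells with at least 1000 UMIs the share was 0.0644%, but this cannot decide on depth. Only 2 Drop-seq cells carried the label, so their share could hardly rise at a higher minimum. An upper limit on genes per barcode was tried on the nuclei, and without barcodes above 1998 genes the lowest nucleus share was 1.63% (1.2 to 2.17). The same limit thus leaves most podocyte nuclei in place. It cannot decide for whole cells, because the Drop-seq library holds no barcode above 1998 genes and a podocyte cell may show more genes than its nucleus. Loss of podocytes in digestion or sorting is a hypothesis that no library here tests.

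Proximal tubule transporter and metabolism genes were lower in UUO. Fewer proximal tubule nuclei as the whole source is argued against by the median of -3.29 within the class, and free RNA by a log2 ratio of -2.44 for the list level inside the class less that outside it. Sex as the whole cause is argued against: UUO against sNucDrop-seq nuclei, which match it in Xist and Y-linked transcripts, was at -5.38 (-6.51 to -3.38), and the list was not as much higher in the 2 Xist-high healthy libraries than in sNucDrop-seq as sex alone would need (-0.92 in 10x and -0.47 in DroNc-seq, upper bounds -0.18 and 0.24), unless platform differences of like size cancelled it in both. Sex as a part of the cause cannot be told apart from UUO, since Xist (log2 -11.67) and the 4 Y-linked genes (7.37) differ in opposite directions, as the bound written beforehand required, and the healthy libraries that differ in them also differ in platform. Injury by obstruction therefore stays a hypothesis, with a part for sex open.

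As a separate hypothesis, healthy nuclei labelled MC may match UUO nuclei labelled Fib.1. The MC profile correlated best with Fib.1 among the UUO labels in each nucleus library, with r across genes of 0.492 in sNucDrop-seq (7485 genes), 0.565 in DroNc-seq (7263) and 0.249 in 10x (7132), and genes are not independent replicates. In sNucDrop-seq and DroNc-seq, the genes that led MC nuclei included Pdgfra, a receptor of stromal cells, and Abca8a. By the same comparison, healthy nuclei labelled as descending limb matched Fib.2 best in sNucDrop-seq (0.176) and DroNc-seq (0.297) and the descending and thin ascending limb label in 10x (0.340), so a shared label name across the 2 tables does not ensure one cell type.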
